A study of Homo sapiens with 2 samples.

How the data were processed

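Nascent strand DNA from 2 libraries of U2OS cells, collected 2 hours after release from a double thymidine block, was sequenced. Per the labels' protocols, DNA was size-fractionated and treated with exonuclease, and libraries were made from the purified product. The submitters' processing notes name BWA, MACS2 and the genome build hg19, without versions or parameters. Use of a control library in peak calling is not given in the sources used here.

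The first deposited file is a broad peak list without a header. Every peak name in it carries the library name that the labels give to replicate 1, and names repeat where a peak is cut into pieces. The fold enrichment, the −log10 p and the −log10 q deposited by the authors have 1 value per peak name, so they describe the whole peak of replicate 1 and not the piece or replicate 2. The deposited score was the whole part of 10 times the −log10 q in 99.97% of lines and was not used further. The lowest −log10 q in the list was 1.31. The other 6 deposited files are interval lists, 1 per replication timing class, whose score column holds the constant 1000 and carries no measurement. The timing data and the rule that assigned the classes are not given in the sources used here. Starts of the timing intervals coincided with the start of a shared piece in 2.35% of cases and ends with an end in 1.85%, as intervals that span the peaks of both libraries would give. Of the intervals, 6 were under 20 bp wide. Interval numbers ran to 162892, and 1023 of them were in none of the 6 lists.

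Each named interval was counted once. A name that stood on 2 lines (21763 names) was taken as the span of both. Of these, 21360 had identical ends, 401 differed by 1 bp at 1 end and 2 were separate pieces. All but 2 were in the very early list. The interval, not the line, was taken as the unit after the repeats were seen, and results with every line counted are given as an alternative. Exact coordinates could not join the 2 kinds of list, so each interval took the enrichment of the replicate 1 peak that shared most bases with it, at least 1 bp; 149 intervals had none. Width is the length of the interval. Spacing is the distance from the end of an interval to the start of the next on the chromosome, where both had the same class. Retention was computed from the numbers of the replicate 1 peaks, which rise along every chromosome. Of the numbers spanned by neighbouring peaks that overlap named intervals of the same class, it is the share whose peak overlaps a named interval. This assumes that peaks were numbered consecutively. Listed peaks that overlap no named interval count as not retained, and 2765 pieces of the list, contigs included, overlapped none. For whole chromosomes every listed peak counts as retained. Density is the number of intervals per window of 1 Mb, over windows that held at least 1 interval.

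For each comparison of 2 classes, the median of a measure was taken on each of chromosomes 1 to 22 and X with at least 20 intervals in both classes. The mean over chromosomes of the log2 ratio of these medians (for retention and shared bases, the difference in percentage points) was tested with a two-sided sign-flip permutation test with 100000 resamples, and again without each chromosome in turn with 2000. Chromosomes are not biological replicates, and the test asks whether a difference recurs over the genome within 1 peak set. Values were adjusted by the Benjamini-Hochberg method over 24 planned comparisons (width, enrichment, −log10 q and spacing, each for very early against very late and for each class against the next), over 12 added ones (retention and shared bases), and within the 3 chromosome-end tests and the 3 correlations. Retention, shared bases, chromosome ends and the correlations across chromosomes were chosen after the data were examined. The test was checked on simulated data for very early against very late widths, with widths of 161770 intervals shuffled within chromosomes and fewer resamples. In 200 simulations it made 11 calls (5.5%) without a difference, and with very early widths raised 1.2-fold it made 200 calls and recovered a mean ratio of 1.20. The shuffling removed any likeness in width between neighbours and gave every chromosome the same shift. In the data the log2 ratio of this contrast had an SD of 0.35 over chromosomes. The 200 calls therefore do not measure the power in these data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

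The alternatives were a −log10 q of at least 5, merging of same-class intervals within 100 bp, autosomes only, intervals of at least 200 bp, the 2 earliest against the 2 latest classes, and the mean of log10 distance. Chosen after the data were examined were every line counted, removal of the first and last 5 Mb of each chromosome, the highest fold among overlapping peaks, and neighbours of any class. The 5 Mb were counted from the first and last interval on a chromosome, not from the chromosome's own ends. The rule for naming regions was the 3 intervals with the highest fold enrichment in each class. The runs with most intervals, the densest windows, the longest stretches without an interval and the chromosomes at the extremes were chosen after their values were seen. Planned comparisons by gene, promoter, gene list, GC content, G-quadruplex motif and random position were not analysed here, because no hg19 sequence or annotation was used and coordinates were not moved between builds. The agreement of the libraries' own enrichments was not analysed here, because the list carries those of replicate 1. Chromosome Y, the mitochondrial genome and 62 contigs entered no test, and the class counts and shares include the 95 intervals on chromosome Y and the 4 on the mitochondrial genome. Coordinates are 1-based.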

Results

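Nascent strand sequencing maps where DNA replication starts by isolating short, newly made DNA whose RNA primer protects it from lambda exonuclease, an enzyme that digests DNA strands lacking such a primer. It was applied here to U2OS, an osteosarcoma cell line, released for 2 hours from a double thymidine block that holds cells at the border of G1 and S phase. The 2 libraries form 1 group, and no unsynchronised or undigested control was analysed here. The data analysed are 1 list of broad peaks shared by both libraries and 6 lists in which the shared intervals are sorted by replication timing, from very early to very late. The question that this design poses is how the nascent strand intervals of early S phase are distributed over the timing classes and whether their properties differ between classes. The number of reads behind each peak is unknown, so no interval for read depth can be given. No label states that the 2 libraries came from separate cultures. Both libraries enter every value below as 1 intersected set, so the errors given are spreads between chromosomes within that set and not between biological replicates.

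The shared peak list held 199201 pieces that covered 84.5 Mb and came from 164008 peaks of replicate 1. The peaks of replicate 1 were numbered along the genome up to 230496, so at most 71.2% of them were retained in the intersection. A retained peak had a median fold enrichment of 4.73, with quartiles of 3.79 and 6.37 and a maximum of 319. These enrichments are the authors' values for the peaks of replicate 1. Replicate 2 cut 24907 of the retained peaks (15.2%) into 2 or more pieces. The 6 timing lists together named 161869 intervals, with a median width of 558 bp and a total of 142.7 Mb. Peaks of both libraries covered 57.6% of the bases in these intervals.

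Most intervals lay in the earlier part of the timing programme, and the mid early class was the most populous. It held 48275 of the 161869 intervals, or 29.8% (exact 95% binomial interval 29.6% to 30.0%). The early class followed with 41887 intervals (25.9%), then the mid late class with 36095 (22.3%) and the very early class with 23091 (14.3%, exact 95% interval 14.1% to 14.4%). The late class held 9030 intervals (5.58%) and the very late class 3491 (2.16%). The 3 earlier classes together made up 70.0% of the intervals, against 7.74% for the late and very late classes together. By covered sequence the order was unchanged, from 46.6 Mb in the mid early class to 2.16 Mb in the very late class. These counts take each named interval once. The very early list printed 21761 of its 23091 names (94.2%) on 2 lines, and by lines it held 44852 entries (24.4% of 183632) and ranked above the early class. The binomial intervals cover counting error only and treat the counted intervals as independent. Of neighbouring pairs 88.5% had the same class, so the binomial intervals are likely too narrow. The amount of genome that each timing class occupies was not used here, so the shares are not densities.

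**Figure D1:**
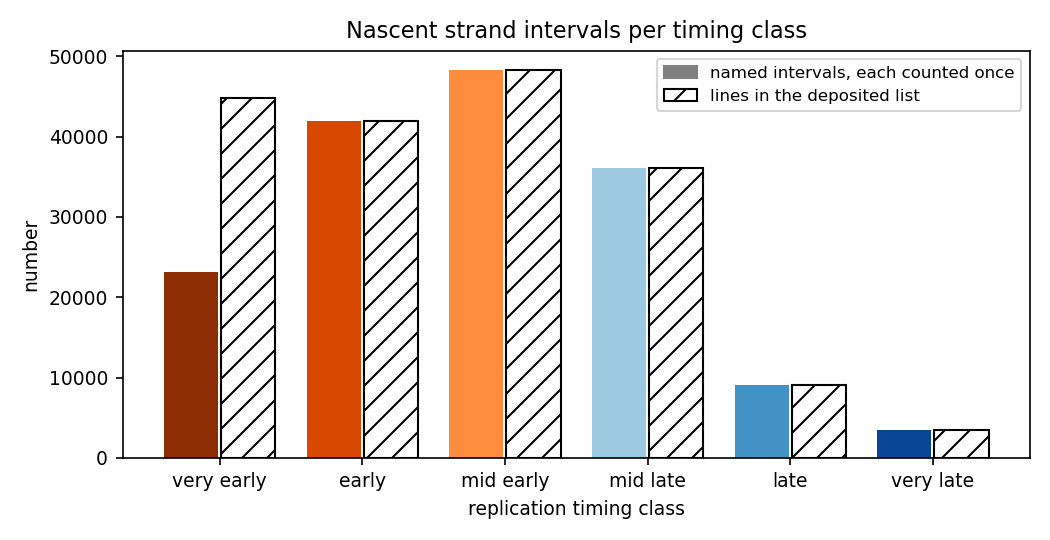
Number of nascent strand intervals (vertical axis) in each of the 6 replication timing classes (horizontal axis). Filled bars count each named interval once and hatched bars count lines of the deposited lists; the 2 differ in the very early class, with 23091 names against 44852 lines.

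Very early intervals were wider, slightly more enriched and closer together than very late ones. The median width on a chromosome was 498 ± 55.8 bp in the very early class and 406 ± 78.4 bp in the very late class (mean ± SD, n = 21 chromosomes), a ratio of 1.24, with the very early class wider on 17 of 21 chromosomes (two-sided sign-flip permutation test, adjusted p = 8.23e-04). The median fold enrichment was 4.54 ± 0.15 against 4.33 ± 0.17, a ratio of 1.05 that held on 16 of 21 chromosomes (permutation test, adjusted p = 7.75e-04). The distance to the next interval of the same class was 2.92-fold longer in the very late class and was longer on 19 of 21 chromosomes (permutation test, adjusted p = 1.31e-04). Over chromosomes, this distance had a median of 3086.5 bp for very early intervals (n = 23) and 10134 bp for very late ones (n = 21). The very late distances ranged from 2806.5 bp on chromosome 18 to 203421 bp on chromosome X. Among intervals with a −log10 q of at least 5 the ratio of enrichments was no longer past the threshold (log2 ratio 0.026, permutation test over 19 chromosomes, adjusted p = 0.128). The −log10 q and the fold belong to the same peak, so this cut is not independent of the enrichment compared, here and below.

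**Figure D2:**
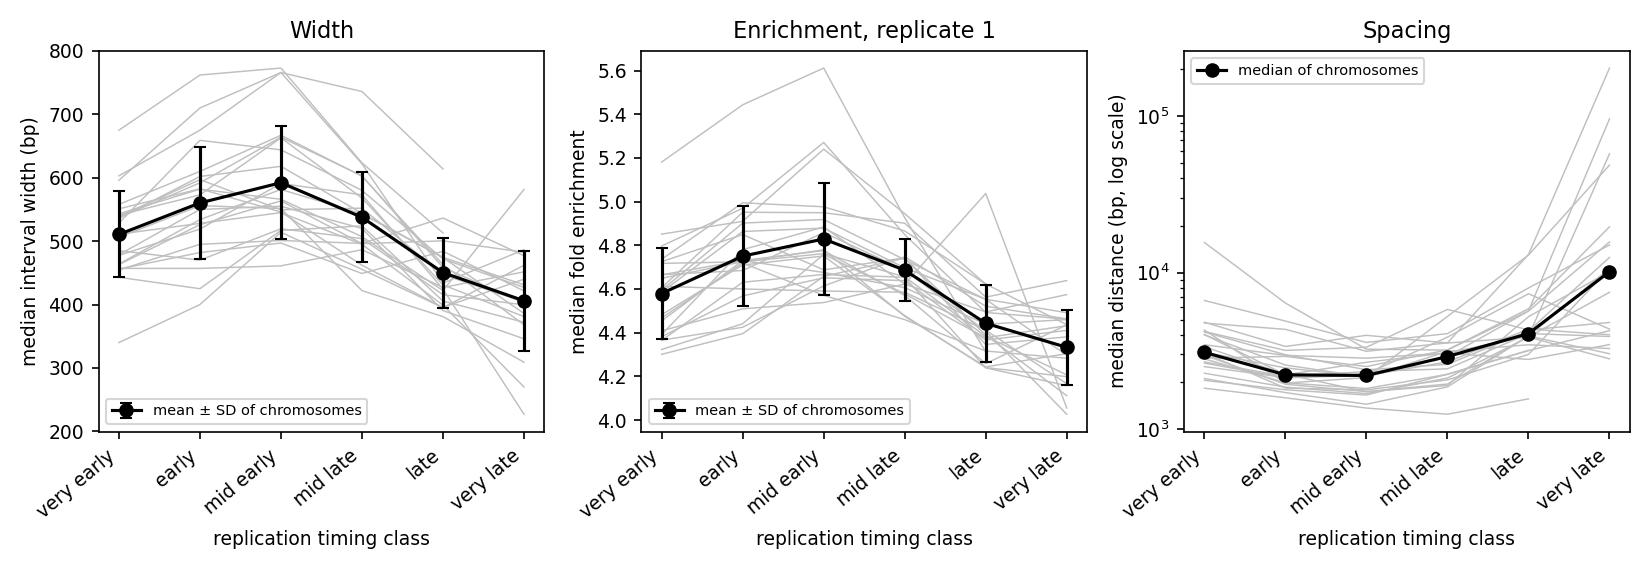
Median interval width in bp, median fold enrichment of replicate 1 peaks and median distance to the next interval of the same class in bp (log scale), by replication timing class. Each grey line is 1 of 23 chromosomes and is drawn for classes with at least 20 intervals; black points are the mean ± SD over chromosomes for width and enrichment and the median over chromosomes for distance. The highest means for width and enrichment are in the mid early class, at 592 bp and 4.83-fold.

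The change across the timing programme was not monotonic, with wider, more enriched and closer intervals in the early and mid early classes than at either end of the programme. Mid early intervals had the largest median width on 15 of 23 chromosomes, the highest median enrichment on 13 of 23 and the shortest spacing on 13 of 23. Width rose from 511 ± 67.8 bp in the very early class to 560 ± 88.3 bp in the early class and 592 ± 89.1 bp in the mid early class. It then fell to 538 ± 70.9 bp in the mid late class and 450 ± 55.0 bp in the late class (mean ± SD, n = 23 chromosomes). Enrichment followed the same course, with 4.58 ± 0.21, 4.75 ± 0.23, 4.83 ± 0.26, 4.69 ± 0.14 and 4.44 ± 0.18 in the 5 classes from very early to late. Among intervals with a −log10 q of at least 5, neither the rise in enrichment from early to mid early nor the fall to mid late passed the permutation test (adjusted p = 0.078 and 0.0708). Very early intervals were narrower than early ones on 20 of 23 chromosomes (ratio 0.914) and less enriched on 22 of 23 (ratio 0.964; permutation test, adjusted p = 6.0e-05 for both). They lay 1.38-fold farther apart, on 22 of 23 chromosomes (permutation test, adjusted p = 6.0e-05). The −log10 q was lower in the very early than in the early class on 22 of 23 chromosomes (log2 ratio −0.11, permutation test, adjusted p = 6.0e-05). Steps from early to mid early were smaller and also passed the permutation test, with adjusted p = 0.00284 for width and 0.0124 for both enrichment and spacing. They were lost in several settings. Without the first and last 5 Mb the log2 ratios were −0.017 for width, −0.012 for enrichment and 0.058 for spacing (permutation tests, adjusted p = 0.614, 0.382 and 0.403). The mean of log10 distance gave 0.078 for spacing (permutation test, adjusted p = 0.0726). From mid late to late, intervals became 0.839-fold as wide and 1.63-fold more distant (permutation test, adjusted p = 6.86e-05 for both). In the last step, from late to very late, intervals became 2.19-fold more distant on 15 of 21 chromosomes (permutation test, adjusted p = 0.00106), which also passed in all 8 alternatives tried. This step passed the permutation test for width and enrichment at adjusted p = 0.0345 and did not pass it for −log10 q (adjusted p = 0.0733), which passed in the other 5 comparisons. Without the first and last 5 Mb it passed for neither width (log2 ratio 0.022, adjusted p = 0.778) nor enrichment (0.015, adjusted p = 0.614, permutation tests). It was also lost on autosomes only (adjusted p = 0.0665 for width and 0.0542 for enrichment), for width with intervals of at least 200 bp (0.169) and for enrichment at a −log10 q of at least 5 (0.129, permutation tests). Without chromosome 14 its width difference had an unadjusted p of 0.068, and without chromosome 4 its enrichment difference had 0.069. All tests were two-sided sign flips over chromosomes. Except where p is called unadjusted, values were adjusted over the 24 comparisons. In an alternative setting they were adjusted over the comparisons run in it, which were 6 for the mean of log10 distance.

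The 3 most enriched intervals of each class, chosen by a rule fixed before the data were examined, reached far above these medians. Positions are in hg19, and the genes, repeats and copy number at these positions were not analysed here. Each fold is that of a replicate 1 peak. Peaks of both libraries covered from 33.3% (the top very late interval) to 98.6% (the very early interval on chromosome 13) of the interval. The highest enrichment of all, 319-fold, belonged to a mid late interval on chromosome 11 from 76403529 to 76404655. The next mid late intervals lay on chromosome 11 from 6677187 to 6678021 at 256-fold and on chromosome 18 from 77671028 to 77673349 at 234-fold. In the very early class the top interval lay on chromosome 10 from 99438625 to 99438769, only 145 bp wide, at 200.02-fold. It was followed by chromosome 16 from 3899374 to 3899499 at 168-fold and chromosome 13 from 110076471 to 110076690 at 157-fold. The early class was led by chromosome 16 from 29319950 to 29321945 at 198-fold, then chromosome 20 from 62465674 to 62469444 at 144-fold and chromosome 1 from 12030586 to 12031790 at 115-fold. Mid early intervals reached 140-fold on chromosome 2 from 25054486 to 25055067, 137-fold on chromosome 2 from 11776690 to 11777420 and 128-fold on chromosome 1 from 31124036 to 31125445. In the late class the top intervals were on chromosome 16 from 23419304 to 23419836 at 169.8-fold, chromosome 1 from 175068406 to 175068890 at 109-fold and chromosome 20 from 23617928 to 23619487 at 99.3-fold. The very late class was led by chromosome 10 from 132541052 to 132541462 at 82.0-fold, chromosome 5 from 8580967 to 8581630 at 64.1-fold and chromosome 10 from 132001973 to 132002187 at 60.0-fold. Intervals of 20-fold or more made up 1.006% of the mid early class (485 intervals), 0.984% of the mid late class (355) and 0.848% of the early class (355). They made up 0.765% of the late class (69), 0.724% of the very early class (167) and 0.659% of the very late class (23). These shares were not tested.

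Neighbouring intervals mostly had the same timing class. Of 161747 neighbouring pairs on chromosomes 1 to 22 and X, 143176 (88.5%) had the same class. Of the 18571 changes of class, 17869 (96.2%) were to the adjacent class, and 41 skipped 2 or more classes. Replication timing varies over stretches far longer than the spacing of the intervals, so such shares could arise from the classification alone. This was not tested, and no chance value was computed. Uninterrupted runs of very early intervals had a median of 5 intervals over 41.5 kb, and runs of very late intervals a median of 2 intervals over 26.2 kb. The run with most intervals was very early, with 184 intervals on chromosome 7 from 100929080 to 101590287, a span of 661 kb. Among mid early runs the most was 155 intervals, on chromosome 12 from 113543172 to 114200745. Among very late runs it was 97 intervals, on chromosome 7 from 56402716 to 57487004, which spanned 1084 kb.

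Chromosomes differed widely in how many intervals they held and when those replicate. Chromosomes 22, 19, 20 and 17 were the densest, with medians of 198.5, 164, 126 and 113 intervals per 1 Mb window that held any, and chromosomes X, 13, 4 and 21 the sparsest, with 6, 8.5, 10 and 13. The 3 earlier classes made up 86.3% of the intervals on chromosome 17 and 81.9% on chromosome 19, both known as gene-rich. They made up 48.9% on chromosome X, 49.0% on chromosome 4, 51.2% on chromosome 13 and 51.3% on chromosome 18. Some chromosomes broke this order: the share was 78.0% on chromosome 3 and 74.4% on chromosome 21, with 15 and 13 intervals per window, and 65.1% on the dense chromosome 20. Across the 23 chromosomes the share of the 3 earlier classes and the density were correlated (Pearson r = 0.56, permutation p = 0.0056, adjusted 0.0084; Spearman rho = 0.55, permutation p = 0.0066, adjusted 0.0066). Without chromosomes 4 and X, the farthest from the median share, r was 0.52 (permutation p = 0.016). This was 1 of 3 relations computed across chromosomes. The last 5 windows of 1 Mb on each chromosome held a median of 146 ± 69.8 intervals, against 47.5 ± 50.6 in the other windows (mean ± SD, n = 23). The density was higher at that end on 21 of 23 chromosomes, by 4.15-fold (two-sided sign-flip permutation test, adjusted p = 6.0e-05). The intervals there belonged to later classes, with 45.2 ± 22.3% in the 3 earlier classes against 69.3 ± 10.4% elsewhere (lower on 18 of 23, permutation test, adjusted p = 1.05e-04).

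**Figure D3:**
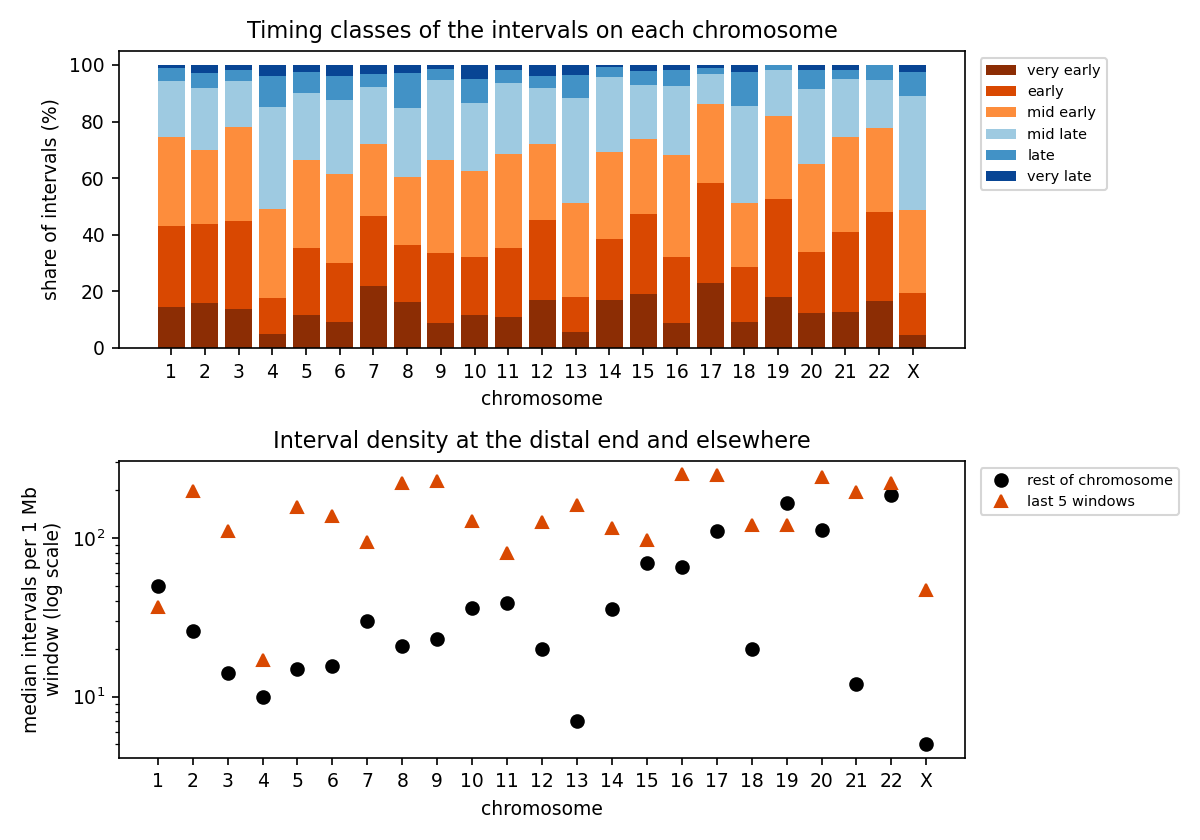
Upper panel, share of intervals (%) in each replication timing class on chromosomes 1 to 22 and X. Lower panel, median number of intervals per 1 Mb window (log scale) in the last 5 windows of each chromosome (triangles) and in its other windows (circles); triangles lie above circles on 21 of 23 chromosomes, with chromosomes 1 and 19 the exceptions.

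A larger share of replicate 1 peaks was retained among very early intervals than among very late ones. Gaps in the numbering of replicate 1 peaks show how many lie between retained neighbours of the same class and were not retained or overlap no named interval. By this measure 72.1 ± 3.52% of replicate 1 peaks were retained among very early intervals and 65.6 ± 7.80% among very late ones (mean ± SD, n = 21 chromosomes). The difference of 6.52 percentage points was in the same direction on 19 of 21 chromosomes (two-sided sign-flip permutation test, adjusted p = 0.0016 over 12 comparisons chosen after the data were examined). The median −log10 q of replicate 1 peaks differed in the same direction, at 4.78 ± 0.38 in very early and 4.29 ± 0.45 in very late intervals. No comparison at like −log10 q was made, so timing class and peak strength cannot be told apart in the differences between classes. Retention was 74.2 ± 3.43% in the early class and 74.9 ± 3.18% in the mid early class (n = 23), and the very early class differed from the early class by −1.80 points (lower on 17 of 23, permutation test, adjusted p = 0.00678). The late class did not differ from the very late class past the threshold (3.28 points, higher on 18 of 21, permutation test, adjusted p = 0.0505). On whole chromosomes, counting every listed peak, retention ranged from 59.5% on chromosome X to 79.7% on chromosome 22. It rose with the density of intervals across the 23 chromosomes (Pearson r = 0.75, permutation p = 6.0e-05, adjusted 1.8e-04; Spearman rho = 0.89, permutation p = 1e-05, the smallest that the resampling can give, adjusted 3.0e-05). Part of this relation is built in, because the density counts intervals that both libraries share. Without chromosomes 19 and 22, r was 0.70 (permutation p = 0.0014). It also rose with the median enrichment (Pearson r = 0.51, permutation p = 0.017, adjusted 0.017; Spearman rho = 0.64, permutation p = 0.0014, adjusted 0.0021), with r = 0.44 without the same 2 chromosomes (permutation p = 0.043). Within an interval, both libraries' peaks covered a median of 60.6 ± 2.09% of the bases in very early intervals and 58.4 ± 3.04% in very late ones (n = 21), which did not pass the permutation test (adjusted p = 0.0505). A peak of replicate 1 that was not retained has no position of its own in the list, so its class was taken from its neighbours.

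**Figure D4:**
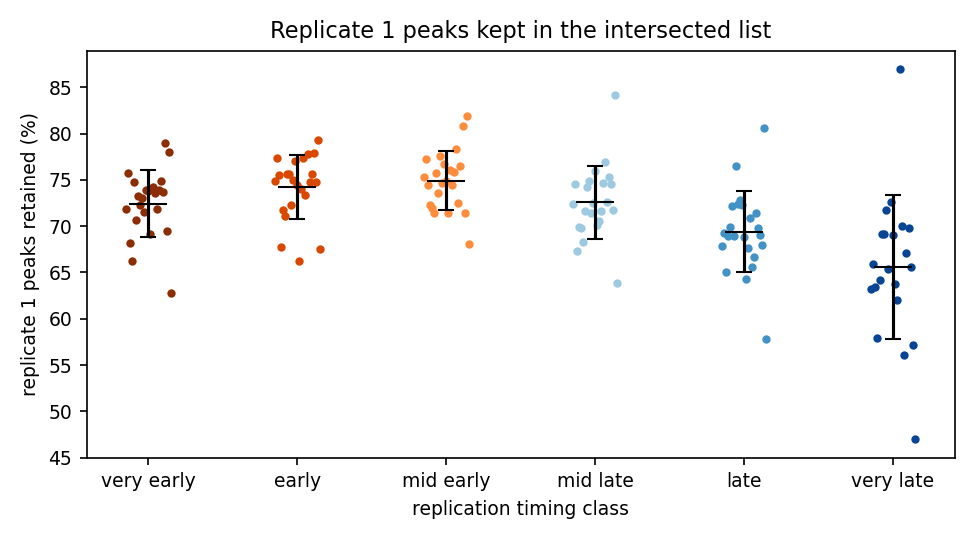
Share of numbered replicate 1 peaks (%) that were retained and overlap a named interval, between neighbouring intervals of the same class, by replication timing class. Each point is 1 chromosome with at least 20 such neighbours and black marks are the mean ± SD over chromosomes; the mean is 74.9% in the mid early class and 65.6% in the very late class.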

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

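The peaks that follow lie on sequences outside the tests across chromosomes, and were listed because their number exceeds the 3 that a count of 0 would allow. The mitochondrial genome held 10 pieces of 4 replicate 1 peaks, between positions 24 and 16502, with fold enrichments of 1.95 to 3.795. All 4 mitochondrial intervals were in the very late list, although mitochondrial DNA is not part of the nuclear timing programme. Chromosome Y held 107 pieces, with a median fold enrichment of 5.36 and a maximum of 16.5, and 95 named intervals on it were in the timing lists. Whether these pieces stem from a Y chromosome in these cells was not tested. These 95 and the 4 mitochondrial intervals are within the 161869 behind the class counts and shares. Contigs of alternative haplotypes held 533 pieces, with a maximum enrichment of 33.5-fold, and unplaced or unlocalised contigs held 499 pieces, with a maximum of 43.8-fold. The timing lists held 0 intervals on these contigs.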

How the results depend on the processing

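Counting every line, leaving out the first and last 5 Mb, the highest overlapping fold, neighbours of any class, and all alternatives for chromosome ends, retention and shared bases were chosen after the data were examined. Of 169 alternative values of the class ratios (6 contrasts of width, enrichment, spacing and −log10 q) and of the chromosome-end density ratio, 155 kept their direction and their side of the threshold, 14 kept the direction and no longer passed, and 0 reversed. Some of the 155 could hardly change. Merging within 100 bp left 161816 of 161869 intervals, and counting every line barely alters contrasts without the very early class. The 155 also include values that did not pass in the main setting. An example is −log10 q of late against very late, at adjusted p = 0.0733 and, without the first and last 5 Mb, 0.615 (permutation tests). Without the first and last 5 Mb the log2 ratio of early over mid early was −0.017 for width, −0.012 for enrichment, 0.058 for spacing and −0.023 for −log10 q, and that of late over very late was 0.022 for width and 0.015 for enrichment. At a −log10 q of at least 5 the enrichment ratio was 0.026 for very early over very late (permutation test, adjusted p = 0.128), −0.017 for early over mid early, 0.019 for mid early over mid late and 0.031 for late over very late. Late over very late was also lost on autosomes only (width 0.12, enrichment 0.034) and for width with intervals of at least 200 bp (0.082). The mean of log10 distance gave 0.078 for the spacing of early over mid early. The cause of these 14 was not tested. For enrichment at a −log10 q of at least 5, the cut itself is not independent of the enrichment compared. For very early over very late the log2 ratio of widths ranged from 0.22 to 0.31, that of enrichments from 0.026 to 0.073 and that of distances from −1.85 to −1.35. The 2 earliest against the 2 latest classes, a pooled contrast, gave 0.30 for width, 0.090 for enrichment and −1.003 for distance. Its p-values were not adjusted. For retention and shared bases only autosomes were tried, and 11 of 12 values kept direction and side; the shared bases of early minus mid early, not past the threshold in either setting, went from −0.015 to 0.020 points. The very early share of intervals, 14.3%, became 24.4% with every line counted, 16.1% without the first and last 5 Mb of each chromosome, and 13.8% at a −log10 q of at least 5. With the same 3 settings the mid early share was 26.3%, 29.4% and 31.3%, and the 3 earlier classes together made up 73.5%, 73.2% and 71.9%. Intervals of at least 200 bp gave 30.1% for the mid early class and 70.4% for the 3 earlier classes, and autosomes only gave 70.3% for the latter. Counting every line gave no value for very early spacing, because a repeated interval overlaps itself. Alternatives for gene, promoter, base composition, motif, random position and library agreement results were not run. No paired analysis was possible because the series holds 1 group, and leaving out a library was not run because only their intersection was analysed. The depth of the libraries is unknown, so whether more reads would add late intervals cannot be read from these lists.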

Other observations

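Dense and empty regions marked the extremes of the map, and were chosen after their values were seen. The median window of 1 Mb held 26 intervals (quartiles 8 and 84.8, 2842 windows). The densest held 311 intervals on chromosome 3 from 13000001 to 14000000, followed by 309 on chromosome 2 from 121000001 to 122000000. A window on chromosome 22 from 37000001 to 38000000 held 286 intervals, of which 100% were in the 3 earlier classes, whereas in the window on chromosome 5 from 1000001 to 2000000 that share was 51.5% of 303. The 40 longest stretches without an interval ran from 1.62 to 21.3 Mb, and 52 of their 80 flanking intervals (65%) were late or very late. Those 2 classes held 7.74% of all intervals. They also had the longest median same-class spacing, 3902.5 and 6206.5 bp, so choosing the longest stretches favours them. Of these stretches 7 were on chromosome X, including 31090270 to 34674293, and 4 on chromosome 18, including 36295157 to 39997397. Assembly gaps and centromeres were not marked here, so the stretches include any that fall in them.

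In the 3 patterns below, the tests of repeated lines, of names listed once and of the classes at chromosome ends were chosen after their results were seen, and the others before.

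The very early list was about as long as the mid early list by lines but held far fewer intervals. Of its names 94.2% stood on 2 lines, against at most 0.0024% in any other list, and 401 repeated names differed by 1 bp at 1 end. This fits a list joined from 2 nearly identical sets of very early segments. The 1330 names listed once lay first or last in a run of very early intervals in 37.8% of cases, against 16.4% of names listed on 2 lines, so the 2 sets may have differed slightly in extent. A count of lines would put the very early class above the early class, which has more intervals by name (41887 against 23091).

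Very early intervals were narrower, less enriched and farther apart than early ones. Chromosome ends were argued against as the whole cause: without the first and last 5 Mb the log2 ratios were −0.095 for width (from −0.13), −0.042 for enrichment (from −0.053) and 0.42 for distance (from 0.47), each past the threshold. The 5 Mb were counted from the outermost intervals. Where the first window held no interval, the cut at the start began inside the chromosome. Cutting at the edges of timing segments was argued against too, as the width ratio was −0.16 without the first and last interval of each run. Within deciles of replicate 1 enrichment the ratios were −0.080 for width and 0.43 for distance. Enrichment at this resolution may account for part of the difference in width and little of that in spacing. Deciles are coarse and enrichment in replicate 2 was not matched, so a larger part for weaker enrichment stays open. Base composition, copy number and the progress of forks by 2 hours after release stay open and were not tested, and no biological explanation was tested because the design has 1 group.

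Distal chromosome ends were denser in intervals although the intervals there belonged to later classes. The mid early and early classes, which had the shortest median spacing, made up 40.9% of intervals there and 55.1% elsewhere (a change of −14.2 points, lower on 18 of 23 chromosomes, sign-flip permutation p = 0.00214), which argues against a surplus of the densest classes. With intervals within 1 kb merged the log2 ratio was 1.75, from 2.05. This argues against wide zones cut by gaps of up to 1 kb as the whole cause. Over the genome the median same-class spacing was 1999 bp or more in every class, so the merge could not join most neighbours. Zones cut by longer gaps stay open. The other end of the chromosome, on the 18 chromosomes with intervals in their first window, was 2.63-fold denser than the parts away from both ends (higher on 15 of 18, permutation p = 0.00205). Base composition, repeated sequence and incomplete digestion of GC-rich DNA could still account for it, and none of them was tested, because no hg19 sequence was used.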
